A study of Homo sapiens with 4 samples.

How the data were processed

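RNA was measured by sequencing in MOLM13 cells, a human acute myeloid leukaemia line, after 12 h with DMSO (the vehicle), SD70, MI-503, or SD70 and MI-503 together. There were 4 libraries, 1 per group, so the groups were those of the treatment label and no library had a replicate. RNA was taken up in Trizol and libraries were prepared by an Illumina protocol, per the labels' protocols. Doses, the number of cultures, the library kit's strand setting, the read counter and the gene annotation were not given in the sources used here.

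BWA, Bowtie and the hg38 build are named in the submitters' processing notes, without a version and without saying which step each served. The authors deposited 1 table per library with an Ensembl gene identifier and a value for 58735 genes, and the value is read here as FPKM, fragments per kilobase of gene scaled to the size of the library, because of the values themselves, since the header does not name the unit. All 58735 identifiers were found in GENCODE release 29, and multiplying each deposited FPKM by the gene's union-exon length gave whole numbers of reads, within 0.01 of a read, for 100% of the values above 0 once 1 step per library was fixed. The recovered reads came to 15550915 for DMSO, 14695753 for SD70, 15937390 for MI-503 and 15093444 for the combination. The library sizes implied by the deposited FPKM differed by 0.0% from those given by median-of-ratios size factors on the recovered reads, so the deposited values were already scaled between libraries in that way; which tool did this was not given in the sources used here. Gene symbols came from a gene name table, which matched 58207 identifiers, and coordinates are those of GENCODE 29 on GRCh38, the assembly hg38.

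The design fixed a count test for the case of raw counts and another for normalized values, before the data were examined; as the values were FPKM, the latter was used. Levels were taken as deposited, and a fold is on the log2(FPKM + 1) scale with a pseudocount of 1, which understates the change of low genes. Genes with a mean of at least 1 FPKM over the 4 libraries were summarised, which left 12296 genes, of which 9891 were protein-coding. A gene was counted as different between 2 libraries where the fold was at least 2. With 1 library per group no test was possible for these pairs. Beside named genes a ratio of FPKM without pseudocount is given with an exact 95% interval (Clopper-Pearson, conditional on the reads of both libraries). These intervals compare 2 libraries, not 2 conditions, and cover counting error only, and PCR reads without molecular identifiers are not independent molecules. A read in a gene of 1 kb was worth between 0.0641 and 0.0662 FPKM. The departure of a gene is log2 of the combination minus log2 of SD70 minus log2 of MI-503 plus log2 of DMSO, so that 0 stands for a combination equal to the product of the 2 single-agent folds.

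A secondary fit used all 4 libraries: limma's moderated test with a mean-variance trend on log2(FPKM + 1), with a term for SD70 and a term for MI-503, 2-sided, with Benjamini-Hochberg adjustment over the 12296 genes and a threshold of 0.05. It sets 2 libraries with an agent against 2 without it and has 1 residual degree of freedom, which is the departure itself; that departure is taken as error, so the fit says nothing about synergy. Words such as rose and fell are used for genes past this threshold, and higher or lower for values. Tested for SD70 on simulated data with 12296 genes, the fit recovered 61% of 100 genes changed 2-fold and 88% of 100 changed 4-fold, and made 31 false calls, of which 30 were genes under 300 bases and 0 were protein-coding. The same test on genes with a mean of at least 20 recovered reads (11231 genes) recovered 95.4% and 100% of 87 and 89 genes and made 41 false calls, and limma-voom on the reads recovered 79% and 93% with 8. These simulated libraries had an assumed coefficient of variation of 0.1 between libraries, no effect of MI-503 and no departure from additivity. In the real fit the departure is the error, so these rates need not hold for the real calls. Folds of SD70 against DMSO were also tested on simulated data: 69.0% of 100 genes changed 2.5-fold and 95.0% of 100 changed 4-fold passed 2-fold, 100 unchanged genes of 12296 did too, and 95.6% of intervals held the true fold.

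Before the data were examined, 40 gene lists were fixed, among them 6 of markers of other cell types; 1 listed gene had no match, and 1 gene was listed under both its older and its current symbol and counted once. The 34 lists with at least 5 measured members were given a median log2 fold per comparison and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. That percentile describes these libraries and is no p-value. On simulated data 5.0% of 200 random lists lay outside the 2.5 to 97.5 percentile range. Counts of members past the limma threshold are given over all genes tested and adjusted over the list alone.

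Named genes also follow a rule fixed before the data were examined. For genes with a recognised symbol, ribosomal and transfer RNA genes left out, and a mean of at least 5 FPKM (6882 genes), these are the 12 highest and 12 lowest per agent that were at least 1.5-fold the same way in the pair of libraries sharing none, the 12 highest and 12 lowest for the combination, the 8 highest and 8 lowest departures, the 10 smallest p in the additive fit per agent, up to 4 members per list with the largest fold, and 17 genes fixed by name. Genes named outside that rule, such as those behind a small count and further list members, were chosen after their values were seen. Correlations of folds are across genes, which are not independent replicates, so they carry no p. For pairs of comparisons the values given by unchanged libraries with counting noise alone, over 50 simulations, stand beside the observed ones. These libraries were all drawn from the DMSO reads, so a gene without reads in DMSO does not vary in them. Their counts of genes past 2-fold may thus be too small, above all for short genes with few reads. Medians of gene sets signed by direction have bootstrap intervals over genes from 2000 draws.

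Alternatives fixed before the data were examined were scaling to the same FPKM total, median-of-ratios factors, pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, protein-coding genes only and limma without the trend. Added after seeing the data were scaling to the same read total, a mean of at least 20 reads, counting intervals past 2-fold, limma-voom on the recovered reads, and combinations of voom or no trend with other filters. Trends of fold on gene length and GC content were removed by lowess with a span of 0.3. Genes such as SMN1, with its near-identical copy SMN2, HSPE1, SNRPG and PSAT1, with processed pseudogenes, and histone genes may share reads with copies, and overlapping genes on either strand, such as LSP1, ITGB7, DPEP2, SOCS2, POLR3G, ACSS2, TUBA1A, ADGRA2, TM7SF2, ACAT2, JMJD1C, HOXA9, MT-CO3 and CNR2, may share reads with their neighbours, so their values are uncertain to that extent. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.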

Results

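Gene expression was profiled by RNA sequencing in MOLM13 cells, a human acute myeloid leukaemia line that carries the MLL::AF9 fusion, after 12 h with vehicle or with 2 agents alone and together. SD70 has been described as an inhibitor of the histone demethylase KDM4C, and MI-503 blocks the binding of menin to MLL, which the fusion needs to keep its target genes on. The series asks what lies behind a synergistic effect of the pair. It holds 1 library each for DMSO, SD70, MI-503 and the combination, with 15550915, 14695753, 15937390 and 15093444 recovered reads, and 22062, 24165, 22655 and 24299 genes above 0 FPKM. Both SD70 libraries held a larger share of mitochondrial ribosomal RNA (1.5% in SD70 and 1.43% in the combination, against 0.85% in DMSO and 0.93% in MI-503) and of lincRNA and antisense genes (0.83% in each, against 0.61% and 0.64%), and a lower share of protein-coding genes (95.99% and 96.03%, against 97.09% and 96.92%). Because no group had a replicate, differences between libraries have no replicate check, and values below are FPKM in DMSO, SD70, MI-503 and the combination, in this order where 4 are given.

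The direct targets of the agents stayed expressed. MEN1, which encodes menin, stood at 20.3, 13.1, 22.6 and 15.7 FPKM and fell with SD70 (log2 change -0.55 ± 0.12 SE, limma adjusted p = 0.0356). KMT2A, the gene of MLL, was at 2.03, 2.07, 1.87 and 2.17 FPKM, and MLLT3, the gene of the fusion partner AF9, at 1.28, 1.46, 1.27 and 1.39 FPKM. KDM4C was at 3.70, 4.61, 3.79 and 4.25 FPKM, a ratio of 1.25 between SD70 and DMSO (95% counting interval 1.12 to 1.39), and did not pass the limma threshold (adjusted p = 0.306). The related demethylase gene KDM3A rose with SD70 (4.86, 7.54, 4.56 and 6.60 FPKM, adjusted p = 0.0424), whereas JMJD1C fell (28.3, 12.1, 15.5 and 10.8 FPKM, adjusted p = 0.0382). Of 17 measured genes in the list of drug targets and their complexes (median -0.17, percentile 47.87), 1 rose (KDM3A) and 4 fell (MEN1, JMJD1C, KDM1A and PRMT1) with SD70, and the counts were 1 and 4 adjusted over the list alone.

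The first comparison asks what SD70 alone did to these leukaemia cells. Genes of mature myeloid cells were higher in SD70 than in DMSO. CHI3L1, a secreted glycoprotein of macrophages and neutrophils, was 20.9-fold higher (95% counting interval 18.3 to 23.9), and ITGAX, the integrin chain CD11c, 11.2-fold higher (9.89 to 12.8). MEF2C, a transcription factor gene activated by MLL fusions, stood at 0.145 of its DMSO level (0.134 to 0.156), and SOCS2, an inhibitor of cytokine signalling, at 0.111 (0.0974 to 0.126). Genes of MYC-driven growth, DNA replication and mitosis were lower, and genes of cholesterol synthesis and inflammation were higher.

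Of 12296 genes, 1522 (12.4%) differed at least 2-fold between SD70 and DMSO, 739 higher and 783 lower, and 1069 of them were protein-coding (473 higher, 596 lower). The higher share was 48.6%, against 60.1% with libraries scaled to the same FPKM total and 60.8% with the same read total, settings that shift the median of all genes by 0.09 and 0.1 log2 in this comparison. With a pseudocount of 0.1 the count was 2322, with 5 it was 462 (173 higher, 289 lower), and at a mean of at least 5 FPKM it was 886 (297 higher, 589 lower), so the higher share went down to 37.4% and 33.5% in the last 2. In the additive fit of the 4 libraries, limma called 2768 genes for SD70 (966 up, 1802 down, 2384 of them protein-coding), and 5006 had an unadjusted p under 0.05. Limma-voom called 3834 (1865 up, 1969 down), whereas 0 were called without the trend, with no filter, or with voom or no trend and no filter, where the smallest adjusted p lay between 0.0514 and 0.277 and 4769 to 5747 genes had an unadjusted p under 0.05. Genes described below as rising or falling passed the trend-based fit over all genes tested, apart from counts adjusted over the list alone, and these calls were lost in the 4 settings with 0.

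The genes with the highest folds for SD70 that were also higher by at least 1.5-fold in the combination against MI-503 were CHI3L1 (ENSG00000133048, chromosome 1, 203178931 to 203186749), LSP1, H2AC6, DNASE2, ITGAX (ENSG00000140678, chromosome 16, 31355134 to 31382997), ITGB7, H2BC5, CNR2, CYP1B1, BMF, DPEP2 and SEMA6B. All 12 rose in the additive fit. CHI3L1 went from 237 reads in DMSO to 5073 in SD70. LSP1, an actin-binding protein of leukocytes, had 29 and 1088 reads, a ratio of 36.6 (25.4 to 55.0). CYP1B1, a cytochrome P450, rose from 19.8 to 143 FPKM, and BMF, a pro-apoptotic member of the BCL2 family, was 8.83-fold higher (7.75 to 10.1). The 12 lowest were SOCS2 (ENSG00000120833, chromosome 12, 93569814 to 93583487), MEF2C (ENSG00000081189, chromosome 5, 88717117 to 88904257), the pseudogene SPCS2P4, NEFH, HSPE1, DACH1, GAL, ALDH1B1, POLR3G, HPDL, SNRPG and ARHGAP11A, and all 12 fell. DACH1, a transcriptional regulator, stood at 0.211 of DMSO (0.196 to 0.228), POLR3G, a subunit of RNA polymerase III, at 0.173 (0.142 to 0.209), and the mitochondrial chaperonin gene HSPE1 at 0.199 (0.17 to 0.231). Reads of SPCS2P4, HSPE1, SNRPG and the histone genes may be shared with copies elsewhere in the genome.

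The list of MLL-fusion and menin target genes was lower in SD70, with a median log2 fold of -0.59 over 27 measured genes, at percentile 0.02 of matched random lists. MEIS1, a homeobox gene needed by MLL-rearranged leukaemia, fell from 5.84 to 1.45 FPKM (ratio 0.249, 0.216 to 0.287), and its partner PBX3 from 25.5 to 10.6. HOXA9 was at 25.1, 17.8, 18.8 and 16.1 FPKM and did not pass (adjusted p = 0.117), and neither did FLT3 (65.3, 41.6, 48.2 and 51.1 FPKM, adjusted p = 0.328). With SD70, 9 list members fell (MEIS1, PBX3, MEF2C, JMJD1C, SATB1, CPEB2, SOCS2, CDKN2C and FUT4) and 1 rose (RUNX2), or 10 and 1 adjusted over the list alone. Myeloid differentiation genes were higher, with a median of 0.87 over 20 measured of 32 listed genes (percentile 100). The macrophage receptor gene CSF1R went from 3.39 to 17.2 FPKM, the co-stimulatory CD86 from 1.23 to 8.45, and ITGAM, the integrin chain CD11b, from 2.43 to 11.1 (adjusted p = 0.0398). In this list 8 genes rose and 0 fell, and 11 rose adjusted over the list alone. CD14 was at 0.105, 0.171, 0.102 and 0.343 FPKM (3, 5, 3 and 10 reads) and lay under the minimum. Granule genes of immature myeloid cells had a median of -0.12 (percentile 69.24). Among the 11, 2 rose (CST7 and SERPINB1) and 4 fell (PRTN3, ELANE, MPO and RNASE2), the same counts as adjusted over the list alone. PRTN3, the neutrophil protease 3 gene, fell from 3018 to 1567 FPKM and ELANE, neutrophil elastase, from 1812 to 1126. CST7 rose from 29.2 to 69.6 FPKM and SERPINB1 from 27.0 to 57.1.

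Growth and division genes were lower with SD70. MYC itself stood at 181, 83.2, 169 and 130 FPKM and fell (adjusted p = 0.0463), and the list of MYC and nucleolar genes had a median of -1.25 (percentile 0.0), with 27 of 29 measured genes falling and 0 rising, over all genes tested and adjusted over the list alone. LDHA fell from 156 to 44.6 FPKM, the nucleolar NOP16 from 26.8 to 8.11 and ODC1, the first enzyme of polyamine synthesis, from 93.3 to 31.1. DNA replication and S phase genes had a median of -1.23, and 30 of 32 fell by both adjustments, among them UNG (35.3 to 9.59 FPKM) and the helicase gene MCM4 (154 to 49.4). For mitosis and G2/M the median was -0.82 and 25 of 27 fell, or 27 adjusted over the list alone. The cyclin gene CCNB1 went from 86.7 to 36.0 FPKM and the kinase gene PLK1 from 41.3 to 18.9. The cell cycle inhibitor CDKN1A rose from 58.6 to 88.9 FPKM (adjusted p = 0.0277). Heat shock genes (median -1.08, percentile 0.0) had 13 of 16 falling, or 14 adjusted over the list alone, such as HSP90AA1, which went from 459 to 143 FPKM. In the unfolded protein response list (median -0.73, percentile 0.04) 10 of 18 fell, HSPA5 from 188 to 54.4 and MANF from 15.7 to 4.64, and adjusted over the list alone 10 fell and 1 rose. Respiratory chain genes (median -0.63, percentile 0.38) had 16 of 25 falling, or 19 adjusted over the list alone, with ATP5MC1 at 27.6 and 10.3 FPKM. The medians of the next lists lay inside the range of random lists. For glycolysis (median -0.28, percentile 27.37) 7 fell and 2 rose (ALDOC and SLC2A3), against 9 and 2 adjusted over the list alone. Genes encoded by mitochondrial DNA had a median of -0.3 (percentile 37.76) with 7 of 13 falling (9 fell and 2 rose adjusted over the list alone), while the mitochondrial ribosomal RNA share was higher. MT-CO3 went from 9507 to 6571 FPKM. Housekeeping genes had a median of -0.37 (percentile 25.26) with 7 of 15 falling, and adjusted over the list alone 7 fell and 2 rose; ACTB was at 1567 and 985 FPKM.

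Sterol and inflammatory genes were higher in both SD70 libraries. Cholesterol synthesis genes had a median of 0.81 over 23 measured (percentile 100), and 20 rose and 0 fell, or 21 and 1 adjusted over the list alone. HMGCS1, which makes the HMG-CoA of the mevalonate pathway (ENSG00000112972, chromosome 5, 43289395 to 43313512), rose from 11.9 to 64.1 FPKM (log2 change 2.65 ± 0.18 SE in limma, adjusted p = 0.0207). LSS, lanosterol synthase, rose from 10.7 to 43.0, and ACAT2 and MVD rose from 12.0 to 39.4 and from 9.61 to 31.3. They were also among the 10 smallest p in the additive fit for genes that met the naming rule, which were ACSS2, MT-CO3, LSS, HMGCS1, IER3, TM7SF2, ACAT2, MVD, PRTN3 and ARHGAP11A. Ribosomal and transfer RNA genes were not named by that rule. MT-RNR2, the large mitochondrial ribosomal RNA, rose as well (5034, 8467, 5507 and 8391 FPKM) with a smaller p than PRTN3. MT-RNR1, the small one, did not pass (log2 change 0.08 ± 0.07 SE, limma adjusted p = 0.397), against a log2 change of 0.68 for MT-RNR2. Fatty acid synthesis genes had a median of 0.36, with 5 rising (SCD, FADS1, FADS2, ACSS2 and ME1) and 1 falling of 12, or 7 and 2 adjusted over the list alone. ACSS2, which makes acetyl-CoA from acetate, went from 5.68 to 41.6 FPKM, and SREBF1 fell from 55.8 to 33.1. LXR targets had a median of -0.28 (percentile 19.48) over 6, where 1 fell (SREBF1) by both adjustments. NF-kB and inflammatory genes had a median of 1.45 over 11 measured of 24 listed. Of the 11, 10 rose by both adjustments, such as the cytokine CXCL8 (0.524 to 6.74 FPKM) and the NF-kB subunit RELB (1.77 to 11.3). The filter takes the mean over all 4 libraries, so low genes that are higher in SD70, such as CXCL8, pass it more readily. Among 16 measured of 28 matched interferon-stimulated genes (median 0.93) 8 rose by both adjustments, IFI6 from 2.07 to 14.6 and STAT2 from 8.2 to 25.4. Histone genes had a median of 1.48 over 11, with 6 rising and 1 falling (H2AZ1), or 7 and 3 adjusted over the list alone. Antigen presentation genes had a median of 0.73 with 3 of 12 rising (HLA-B, HLA-E and CD74), or 8 rising and 1 falling adjusted over the list alone.

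Further lists moved less evenly with SD70. Of 21 p53 targets (median 0.27, percentile 99.71) 6 rose and 2 fell (AEN and TRIAP1), or 9 and 2 adjusted over the list alone, with BTG2 at 2.95 and 17.2 FPKM and TP53INP1 at 4.84 and 18.7. NRF2 targets (median 0.45) had 6 rising and 2 falling (TXN and PRDX1) of 17, or 8 and 5 adjusted over the list alone, among them HMOX1, heme oxygenase 1, from 0.275 to 4.19 FPKM, and the autophagy receptor gene SQSTM1 from 10.1 to 38.2. Lysosome and autophagy genes (median 0.57) had 6 of 19 rising, or 8 adjusted over the list alone, including the protease gene CTSD (18.4 to 59.2). Iron genes (median 0.47) had 3 rising of 10 by both adjustments, HMOX1 and the ferritin genes FTH1 (63.3 to 194 FPKM) and FTL (2201 to 4831). Hypoxia genes (median 0.29) had 5 of 17 rising, or 6 adjusted over the list alone, and the 5 were PFKFB4, BNIP3L, SLC2A3, VEGFA and KDM3A. Immediate early genes (median 0.29, percentile 97.19) had 5 rising (FOS, JUND, IER2, IER3 and KLF6) and 1 falling (FOSL1) of 14, or 6 and 2 adjusted over the list alone. In the amino-acid and ATF4 stress list (median -0.22, percentile 38.99) 5 rose (DDIT3, SLC7A11, CEBPB, PPP1R15A and WARS1) and 0 fell of 25 by both adjustments. By fold the list was mixed, with 5 members at least 1.5-fold higher and 7 lower in SD70 than in DMSO. Its median departure was 0.71, which the fit takes as error. Pro-apoptotic genes (median 0.03, percentile 81.96) had 2 rising, BMF and BBC3, and 1 falling, BID, and 3 and 1 adjusted over the list alone. Anti-apoptotic genes (median 0.07, percentile 79.86) had BCL2A1 (0.243 to 6.65 FPKM) and CFLAR rising and BIRC5 falling, 2 and 1 by both adjustments. BCL2 (18.4, 12.1, 17.4 and 14.8 FPKM) and MCL1 (73.5, 52.2, 60.1 and 53.1 FPKM) did not pass, at adjusted p = 0.102 and 0.123. Surface receptors of leukaemia cells (median 0.47) had 4 rising of 10, CD52, CXCR4, IL3RA and CD44, with 4 and 1 falling adjusted over the list alone. Stem and progenitor genes (median 0.11, percentile 92.76) had CD244, CD38 and IL3RA rising, 3 of 9 by both adjustments. Metallothioneins had a median of -0.2 (percentile 42.84), where MT1G and MT1E fell, 2 of 8 by both adjustments. Long noncoding and unspliced RNAs (median 0.22, percentile 96.07) had MALAT1 (14.2 to 24.0 FPKM) and NEAT1 rising, with 3 rising and 2 falling adjusted over the list alone. Ribosomal protein genes had a median of 0.17, with 2 of 30 rising (RPS2 and RPS12) and 0 adjusted over the list alone.

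**Figure D1:**
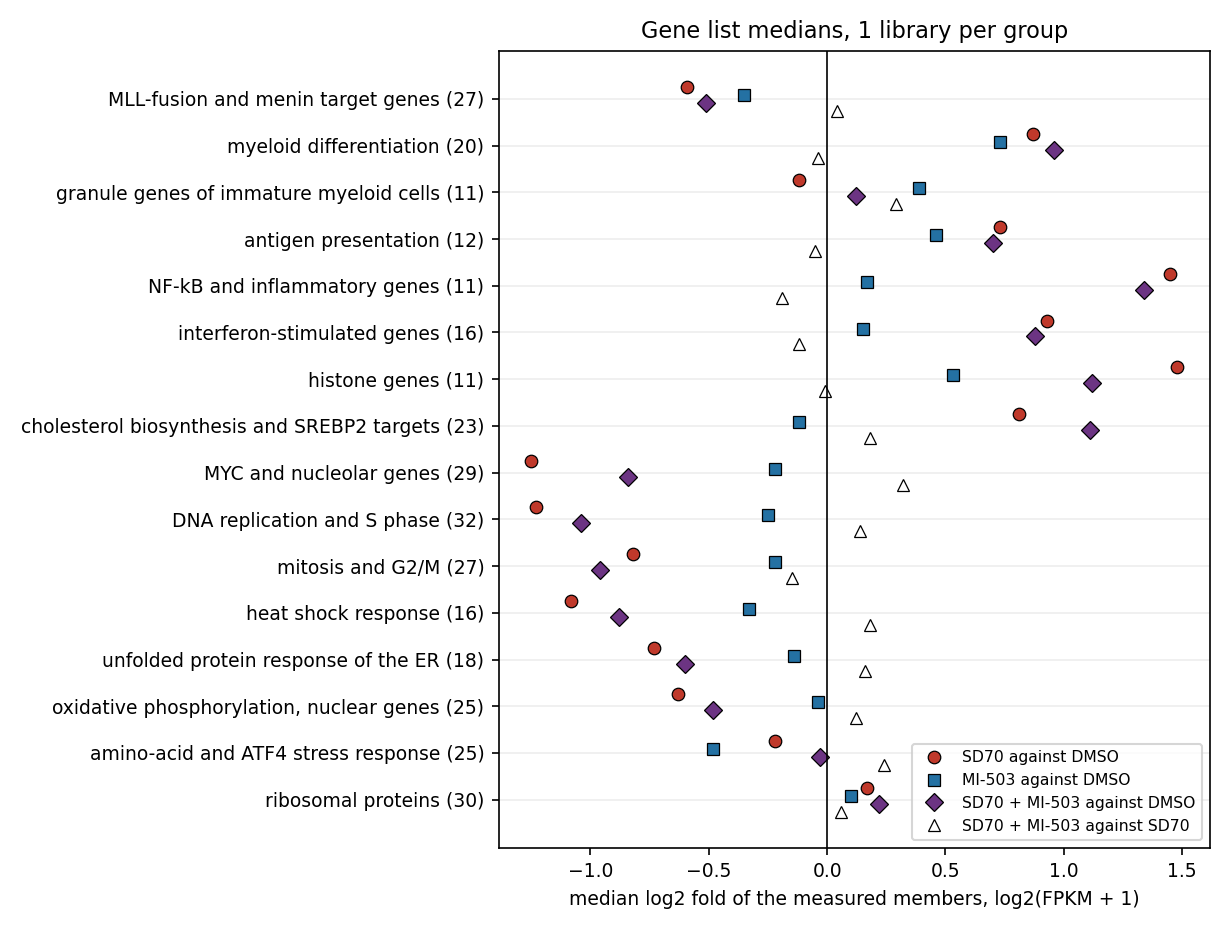
Median log2 fold on the log2(FPKM + 1) scale (x axis) for 16 gene lists (y axis, number of measured genes in brackets), with a symbol for each of SD70, MI-503 and the combination against DMSO and for the combination against SD70. SD70 and the combination lie close together, at -1.25 and -0.84 for MYC and nucleolar genes and 0.81 and 1.11 for cholesterol synthesis, and the open triangles for the combination against SD70 lie between -0.19 and 0.32; each group had 1 library, so no error bars are drawn.

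The second comparison asks what MI-503 alone did at the same time point. Mature myeloid genes were higher and menin target genes lower with MI-503, whereas granule genes were higher with it and in part fell with SD70. CHI3L1 was 4.73-fold higher than in DMSO (95% counting interval 4.11 to 5.46) and ITGAX 2.98-fold higher (2.59 to 3.44), while MEF2C stood at 0.398 of DMSO (0.378 to 0.418) and MEIS1 at 0.542 (0.487 to 0.602). MLL-fusion and menin target genes had a median of -0.35 (percentile 0.0), with SOCS2, MEF2C and CPEB2 at least 2-fold lower. Myeloid differentiation genes had a median of 0.73 (percentile 100), with CYBB, S100A9, ITGAX, MNDA and CSF1R at least 2-fold higher and 12 of 20 at least 1.5-fold higher.

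Of the 12296 genes, 266 (2.2%) differed at least 2-fold, 145 higher and 121 lower, and 181 of these were genes under 300 bases. Simulated unchanged libraries with counting noise alone gave 76.5 genes, of which 72.6 were under 300 bases and 0.1 protein-coding. As these were drawn from the DMSO reads alone, the number under 300 bases may be too small. Only 44 were protein-coding, 33 higher and 11 lower. The 11 lower genes were led by CHAC1 (log2 fold -2.04), DDIT4 (-1.53), CPEB2 (-1.31), MEF2C (-1.26) and SOCS2 (-1.22), and the 33 higher ones by CHI3L1 (2.02), SMN1 (1.81), ITGB7 (1.56) and CYBB (1.53), the last a subunit of the phagocyte NADPH oxidase. SMN1 (ENSG00000172062, chromosome 5, 70925030 to 70953942) was the 1 gene that met the naming rule for MI-503, at 6.22, 4.15, 24.3 and 8.87 FPKM; its reads may be shared with SMN2. The count was 624 with a pseudocount of 0.1, 20 with a pseudocount of 5, 52 at a mean of at least 5 FPKM and 53 where the counting interval had to lie past 2-fold. In the additive fit limma called 0 genes for MI-503, with 401 at an unadjusted p under 0.05 and a smallest adjusted p of 0.692; limma-voom called 0 with 202. At a mean of at least 5 FPKM limma called 1, RNU7-61P, a gene of 61 bases with 5, 8, 15 and 22 reads, named after its values were seen.

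Granule genes of immature myeloid cells were higher with MI-503 whether or not SD70 was present. The list's median was 0.39 against DMSO (percentile 100) and 0.29 for the combination against SD70 (percentile 99.98), and all 11 members were higher in both pairs. MPO, myeloperoxidase, was at 10.3, 6.64, 16.8 and 10.5 FPKM, the protease gene CTSG at 35.8, 41.3, 54.8 and 57.3, and MS4A3 at 18.4, 16.8, 33.1 and 23.2. None passed the limma threshold over all genes tested, and 7 of 11 rose adjusted over the list alone (PRTN3, MPO, CTSG, MS4A3, RNASE3, AZU1 and ELANE). In every other list with measured members, limma called 0 genes for MI-503 over all genes tested and adjusted over the list alone. Amino-acid and ATF4 stress genes were lower in MI-503 (median -0.48, percentile 0.0), with CHAC1, a glutathione-degrading enzyme, and DDIT4, an inhibitor of mTORC1, at least 2-fold lower; DDIT4 stood at 0.283 of DMSO (0.222 to 0.357, 322 and 94 reads). The medians were -0.25 for S phase, -0.22 for mitosis, -0.22 for MYC and nucleolar genes, -0.33 for heat shock, 0.46 for antigen presentation, 0.53 for histone genes and -0.12 for cholesterol synthesis. Immediate early genes had a median of -0.28, with EGR1 at 4.68, 2.9, 1.49 and 4.22 FPKM, and interferon-stimulated genes one of 0.15; these signs turned to 0.01 with no filter and to -0.02 at a mean of at least 5 FPKM.

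The agents are also compared with each other, which asks whether they reach the same genes. Of the protein-coding genes, 31 differed at least 2-fold the same way with each agent, among them CHI3L1, ITGAX, ITGB7, CSF1R, MEF2C and SOCS2 (chosen after their values were seen). Over all genes, 89 were higher and 51 lower with both agents, against 8.7 and 7.7 for independent lists and 14.7 and 10.1 for simulated unchanged libraries that share the DMSO library, and 3 went opposite ways. Across genes the log2 folds correlated with Pearson r = 0.61 (Spearman rho = 0.64, simulated r = 0.51), or 0.72 for protein-coding genes, with a covariance of 0.139 against 0.018 simulated. Both comparisons use the same DMSO library, which cannot be split, so part of the excess may come from it. Over the 44 protein-coding genes that were 2-fold different with MI-503, the fold in SD70 was larger in the same direction, by a signed median of 0.78 log2 (bootstrap interval 0.34 to 0.93).

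Pairs of libraries that share none measured each agent again. For SD70 the folds recurred. SD70 against DMSO and the combination against MI-503 correlated across genes with r = 0.69 (rho = 0.77, simulated r = 0.01), or 0.89 for protein-coding genes, 0.51 with a pseudocount of 0.1 and 0.53 with no filter. In both pairs 186 genes were at least 2-fold higher (20.3 if independent, 4.2 simulated) and 109 lower (12.9 and 3.9), with 35 opposite. HMGCS1 was 5.4-fold higher in the first pair (5.02 to 5.82) and 8.44-fold in the other (7.84 to 9.1), and MEF2C stood at 0.145 and 0.337 (0.309 to 0.366). For MI-503 they did not recur across genes: MI-503 against DMSO and the combination against SD70 had r = -0.12 (rho = -0.17), or -0.22 for protein-coding genes, against 0.01 simulated, with 18 genes at least 2-fold higher in both (1.2 if independent, 4.1 simulated), 14 lower (1.2 and 3.7) and 40 opposite.

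**Figure D2:**
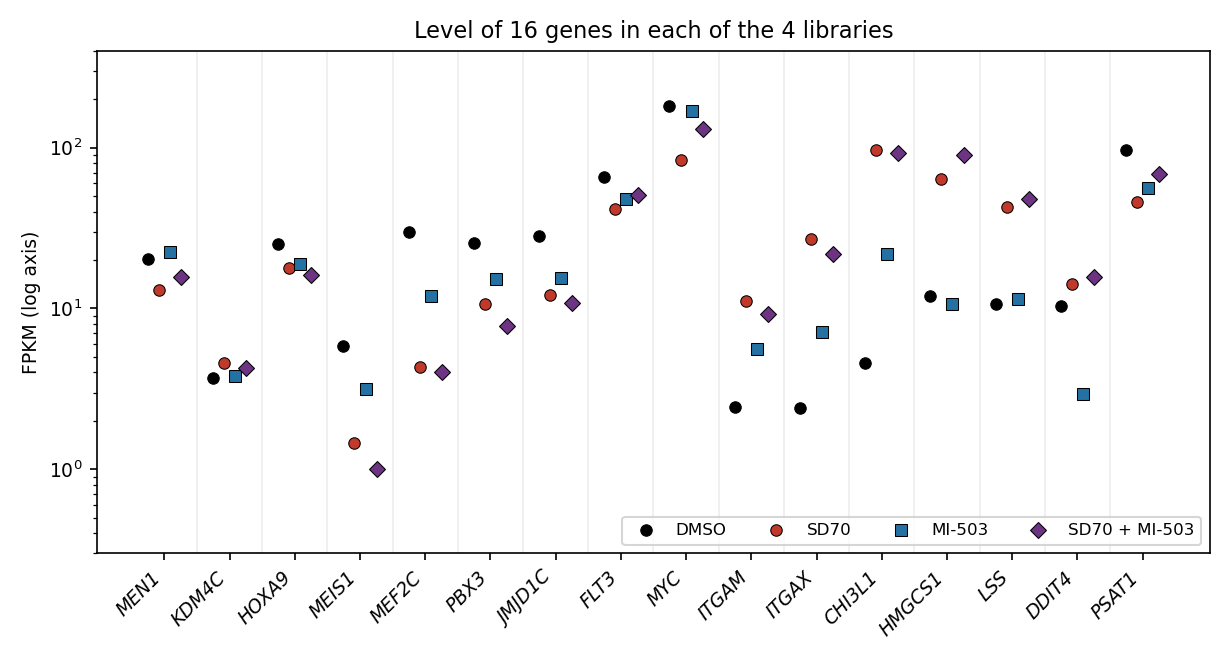
Level of 16 genes (x axis) in FPKM on a log axis (y axis), 1 point per library for DMSO, SD70, MI-503 and the combination. MEIS1 stands at 5.84, 1.45, 3.16 and 1.01 FPKM and HMGCS1 at 11.9, 64.1, 10.6 and 89.7, and there are no replicates and so no error bars.

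The combination is the condition the series is about, and against DMSO it looked like SD70 alone. CHI3L1 was 20.2-fold higher (17.7 to 23.1), HMGCS1 7.55-fold (7.03 to 8.12) and ITGAX 9.01-fold (7.92 to 10.3), whereas MEF2C stood at 0.134 of DMSO (0.124 to 0.145) and MEIS1 at 0.173 (0.146 to 0.204). The list medians were -0.51 for MLL-fusion and menin targets (percentile 0.03), 0.96 for myeloid differentiation (percentile 100), 1.11 for cholesterol synthesis (percentile 100), -0.84 for MYC and nucleolar genes, -1.04 for S phase and -0.96 for mitosis (percentile 0.0 each). For NF-kB genes the median was 1.34 and for interferon-stimulated genes 0.88.

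In all, 1074 genes (8.7%) differed at least 2-fold from DMSO, 612 higher and 462 lower, of which 694 were protein-coding (380 higher, 314 lower); with a pseudocount of 0.1 the count was 1805 and with 5 it was 266. Of the 612 higher genes 482 were also higher in SD70 alone (36.8 if independent, 15.6 in simulated unchanged libraries) and 83 in MI-503 alone (7.2 and 15.8). Of the 462 lower genes 373 were lower in SD70 (29.4 and 10.9) and 37 in MI-503 (4.5 and 9.9), and part of each excess may come from the shared DMSO library. The 12 highest genes were CHI3L1, LSP1, HMGCS1, ACSS2, ITGAX, ITGB7, ADGRA2, CNR2, H2AC6, DNASE2, TUBA1A and H2BC5, and the 12 lowest SPCS2P4, MEF2C, SOCS2, DACH1, SNRPG, ARHGAP11A, CPEB2, CNOT6L, PDCD6IPP1, ZNF521, EMB and NEFH. ADGRA2, an adhesion receptor gene, was 11.7-fold higher (9.6 to 14.3), and EMB, an immunoglobulin-family membrane protein, stood at 0.279 (0.268 to 0.29). Genes at least 2-fold different in the combination and under 1.5-fold in each agent alone numbered 22 higher and 25 lower, and 0 of them were protein-coding. The 1 that met the naming minimum was the pseudogene HMGB1P10, at 6.58, 4.94, 7.62 and 2.64 FPKM (56, 43, 67 and 23 reads), named after its values were seen.

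Adding MI-503 to SD70 gave few 2-fold differences, and most genes that SD70 had shifted lay slightly nearer to DMSO. Of the 1522 genes 2-fold different with SD70, 1285 were nearer and 234 further, by a signed median of -0.22 log2 (bootstrap interval -0.24 to -0.21). The SD70 library enters both folds with opposite signs, which alone gives such a return; the covariance of the folds was -0.093 across genes, against -0.017 in simulated unchanged libraries. CHI3L1 had a ratio of 0.966 between the combination and SD70 (0.929 to 1.01) and MEF2C of 0.926 (0.836 to 1.03), whereas MEIS1 was lower at 0.695 (0.569 to 0.849), PBX3 at 0.735 (0.657 to 0.822), and HMGCS1 higher at 1.4 (1.35 to 1.45). MYC was 1.56-fold higher in the combination than in SD70 (1.5 to 1.63), and MYC and nucleolar genes had a median of 0.32 (percentile 100). The MLL-fusion and menin target list had a median near 0 (0.04, percentile 70.27), myeloid differentiation -0.04 (percentile 4.85), cholesterol synthesis 0.18 (percentile 99.99), ATF4 stress genes 0.24 (percentile 100) and mitosis -0.15 (percentile 0.0). Between these 2 libraries 221 genes (1.8%) differed at least 2-fold, 104 higher and 117 lower, but 178 were under 300 bases and 4 were protein-coding: PCP2 (4.13 to 1.21 FPKM, 51 and 15 reads), H4C12 (6.01 to 2.49, 29 and 12 reads), H2AC20 (0.994 to 3.15, 6 and 19 reads) and SCT (0.177 to 1.94, 1 and 11 reads), named after their values were seen. At a mean of at least 20 reads the count was 17, and 9 had a counting interval past 2-fold. Adding SD70 to MI-503, in contrast, gave 539 genes (4.4%), 337 higher and 202 lower, and 230 protein-coding ones, with cholesterol synthesis genes at a median of 1.12 and NF-kB genes at 1.05. MYC and nucleolar genes had a median of -0.64 there and S phase genes -0.83. The count was 290 at a mean of at least 20 reads, and the intervals lay past 2-fold for 225.

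The last comparison asks whether the combination went beyond the product of the single-agent folds, which bears on synergy at the level of RNA. In these libraries the protein-coding genes that both agents shifted fell short of that product in the direction of their shift. They were picked for their distance from the 1 shared DMSO library, which by itself favours falling short. The lowest departures were -2.07 for CHI3L1, -1.87 for ITGB7, -1.71 for H2AC6, -1.57 for ITGAX, -1.53 for CYBB, -1.52 for YPEL3, -1.50 for ANXA1 and -1.50 for LSP1, all of them higher with each agent alone. The highest departures were RPL29P11 (1.76), SLC7A5P1 (1.70), DDIT4 (1.67), OCSTAMP (1.52), SOCS2 (1.36), PSAT1 (1.35), STAG3L1 (1.34) and POLR3G (1.22), of which all but RPL29P11 and DDIT4 were lower with each agent alone. DDIT4 (ENSG00000168209, chromosome 10, 72273920 to 72276036) was 5.39-fold higher in the combination than in MI-503 (4.32 to 6.79).

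Over the 31 protein-coding genes that were 2-fold different the same way with both agents, signed by that direction, the median log2 fold was 2.18 for SD70, 1.17 for MI-503 and 2.13 for the combination, and the median departure was -1.29 (bootstrap interval -1.48 to -1.18). All 31 fell short of the product in that direction. Counting noise in simulated unchanged libraries gave on average 0.0 such genes per simulation, with a departure of -1.45 in the few that arose. Counting noise thus hardly yields such genes, but a DMSO library deviating by more than that was not simulated. The -1.45 rests on too few genes to compare with the 31. Because a deviating DMSO library would favour such departures, the departure of the 31 does not by itself show an effect below the product. Over all 140 genes shifted by both agents the departure was -1.69, against -1.93 over 24.9 genes in the simulated libraries. There it is no larger than picking genes against 1 shared DMSO library gives, though the simulated libraries held fewer such genes. For the 31 protein-coding genes the departure was -1.82 with a pseudocount of 0.1 and -0.72 with 5. By departure without that sign, 526 genes (4.3%) lay at least 2-fold from the product, 228 above and 298 below. Of these, 108 were protein-coding, 28 above and 80 below. Here a gene lowered by both agents that fell short of the product counts as above, such as SOCS2 (1.36) and MEF2C (1.17). The count was 173 at a mean of at least 20 reads. List medians of the departure were -0.85 for myeloid differentiation (percentile 0.0) and 0.21 for cholesterol synthesis (percentile 97.81). They were 0.34 for MLL-fusion and menin targets, 0.57 for MYC and nucleolar genes and 0.71 for ATF4 stress genes (percentile 100 each). These lists were fixed beforehand and not picked by fold, but the DMSO library enters their departures too. Across 6661 protein-coding genes with a mean of at least 5 FPKM, the combination's log2 fold followed the sum of the single-agent folds with r = 0.97 and a slope of 0.66, against 0.58 and 0.34 in simulated unchanged libraries, in a plot where the DMSO library enters the sum more heavily than the combination's fold. The DMSO library enters each departure with the sign opposite to both single-agent folds, so a deviation of that library moves a departure and the agents' shared folds in opposite directions.

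**Figure D3:**
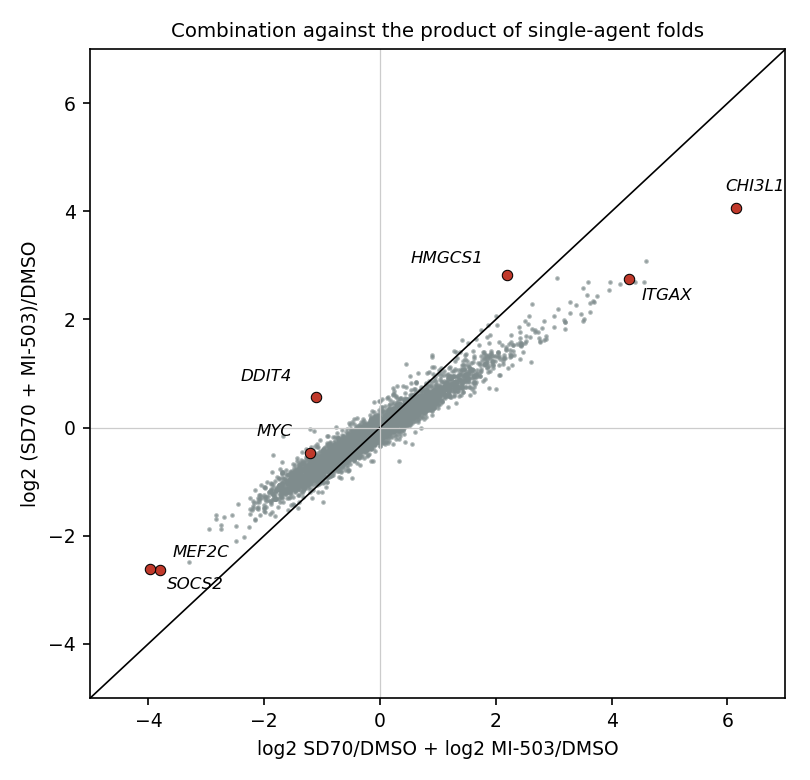
For 6661 protein-coding genes with a mean of at least 5 FPKM, the sum of the log2 folds of SD70 and MI-503 against DMSO (x axis) and the log2 fold of the combination against DMSO (y axis), with 7 genes named in red. On the black line the combination equals the product of the single-agent folds; the points follow a slope of 0.66, with CHI3L1 below the line (departure -2.07) and DDIT4 above it (1.67).

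Markers of other cell types were sparse and mostly under the minimum: 0 of 14 erythroid genes, 1 of 9 B cell genes, 3 of 13 T and NK cell genes, 1 of 7 megakaryocyte genes, 1 of 8 epithelial genes and 0 of 8 fibroblast genes were measured. GP1BA, a platelet receptor gene, was at 2.59, 3.05, 2.43 and 3.0 FPKM, and IGLL1, a pre-B cell gene, at 3.66, 0.572, 1.56 and 2.0 FPKM. NKG7, a granule gene of cytotoxic cells, rose with SD70 (14.3, 54.9, 29.6 and 48.4 FPKM, adjusted p = 0.0356), CD4, which monocytic cells also express, was at 48.7, 61.1, 58.9 and 60.0 FPKM, and TRAC at 10.7, 12.5, 8.66 and 14.0. KRT18 was at 0.967, 2.21, 1.55 and 2.29 FPKM and passed only when adjusted over the list alone. It was the 1 measured epithelial gene, so its p there was in effect unadjusted. In the B cell and megakaryocyte lists limma called 0 genes for SD70 by both adjustments.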

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

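The tests of a deviating DMSO library and of the pseudocount on protein-coding genes alone were chosen only after the result was seen; the other tests in this part were written down before their own results, though the folds of leading genes such as CHI3L1 and HMGCS1 had been seen by then.

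Some genes and lists moved opposite ways with an agent alone and on top of the other agent, each by at least 0.32 log2 (lists by at least 0.2). The difference was not tested, since each effect rests on 1 pair of libraries. For the genes, the naming rule itself favours opposite signs. The departure is an agent's log2 fold on top of the other agent minus its log2 fold alone, and some genes were named for large departures. Others were named for large folds of SD70 against DMSO, 2 libraries that each enter 1 of the MI-503 folds as the reference. For MI-503 on top of SD70 against MI-503 alone, in log2, these were H2AC6 (-0.54 against 1.17), DNASE2 (-0.48 against 1.0), H2BC5 (-0.40 against 1.02), CYP1B1 (-0.48 against 0.83), BMF (-0.46 against 0.91), SEMA6B (-0.35 against 0.97) and YPEL3 (-0.63 against 0.89). The other way round stood NEFH (0.44 against -0.49), HSPE1 (0.48 against -0.67), GAL (0.51 against -0.43), ALDH1B1 (0.67 against -0.35), POLR3G (0.46 against -0.76), PSAT1 (0.57 against -0.78), STAG3L1 (0.52 against -0.82) and the pseudogene SLC7A5P1 (1.21 against -0.49). SD70 on top of MI-503 against SD70 alone gave 1.05 against -0.47 for OCSTAMP and 0.48 against -0.87 for STAG3L1. Among the lists, MYC and nucleolar genes had medians of 0.32 for MI-503 on top of SD70 and -0.22 alone, and ATF4 stress genes 0.24 and -0.48 for MI-503, and 0.43 and -0.22 for SD70.

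The first pattern is that MI-503 and SD70 shifted the same genes the same way against DMSO, while MI-503 added to SD70 moved few by 2-fold. A DMSO library that stands apart, with no effect of either agent, would leave SD70 and MI-503 at the same level. Over all 266 genes the signed median of SD70 against MI-503 was -0.29, which such a library could give. Over the 44 protein-coding ones it was 0.78 (bootstrap interval over genes 0.34 to 0.93), which it could not. A deviating DMSO library with an effect of SD70 alone would also give this difference. The value therefore does not show that MI-503 shifted these 44 genes. With a pseudocount of 0.1 the departure of the genes shifted by both agents grew, from -1.69 to -2.86 over all 140. Over the 31 protein-coding ones it went from -1.29 to -1.82, and to -0.72 with a pseudocount of 5. For genes higher with both agents DMSO lies below both, so a smaller pseudocount enlarges the departure by construction. This test therefore cannot decide on compression of large folds by the pseudocount. For these picked genes the departure may come from picking against the shared DMSO library. In unchanged libraries such picking gives -1.93 over 24.9 genes of all types, fewer than the 140 observed. It gives -1.45 in the few protein-coding genes that arose, too few to compare with the 31. Lists fixed beforehand, such as myeloid differentiation (median departure -0.85, percentile 0.0), were not picked by fold, but the DMSO library enters their departures too. A deviating DMSO library with no effect of MI-503 on menin target genes stays open, since that list lay at percentile 70.27 in the combination against SD70, where the DMSO library plays no part. Equally open, and untested, is that SD70 had already made the changes MI-503 makes.

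The next pattern is the number of genes at least 2-fold different between SD70 and DMSO. Gene length and GC content as the whole cause are argued against, because 93.0% and 89.6% of the 1522 genes still differed at least 2-fold the same way after the trend on length or GC was removed. The higher share of mitochondrial ribosomal and noncoding RNA in both SD70 libraries may reflect the agent or the RNA preparation, and the design gives each library 1 treatment, so the 2 were not separated. An effect of SD70 itself, which the design names, stays as a hypothesis; across protein-coding genes its folds in 2 pairs of libraries that share none correlated with r = 0.89.

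The third pattern is the rise of cholesterol synthesis genes in both SD70 libraries. Scaling between libraries is argued against as its cause, because the list's median of 0.81 was at least 0.92 with libraries scaled to the same FPKM or read total. Lower sterol sensing, with SREBP2 on and LXR off, is a candidate explanation that cannot be told apart from others here: in SD70 against DMSO the LXR target ABCA1 stood at -0.32 log2, and ABCG1 lay under the minimum of 1 FPKM. In the combination against MI-503 the LXR list had a median of -0.42 (percentile 1.46), the direction this explanation asks for, and ABCA1 was lower as well. That list was itself higher in MI-503 than in DMSO (median 0.26, percentile 98.67), so this pair does not settle it. An effect of SD70 on sterol genes by another route stays open and was not tested.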

How the results depend on the processing

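The limma-voom settings, limma without the trend joined to another filter, the read minimum, the read-total scaling and the counting intervals were chosen only after seeing the data; the other settings were fixed before. The cause of these shifts was not tested, except that a stricter filter or a class of genes leaves fewer genes to count at 2-fold. In the order SD70, MI-503 and the combination against DMSO, the combination against SD70, the combination against MI-503, and the departure, the genes at least 2-fold different numbered 2322, 624, 1805, 413, 973 and 1003 with a pseudocount of 0.1, 462, 20, 266, 14, 79 and 90 with a pseudocount of 5, and 886, 52, 572, 17, 207 and 105 at a mean of at least 5 FPKM. With no filter on low values MI-503, the combination against SD70, the combination against MI-503 and the departure gave 527, 562, 878 and 1229, and with a mean of at least 20 recovered reads 64, 17, 290 and 173. Protein-coding genes alone gave 44 for MI-503, 694 for the combination, 4 against SD70, 230 against MI-503 and 108 departures, and counting intervals past 2-fold gave 53, 675, 9 and 225, with no value for the departure. The 2 total-based scalings and median-of-ratios factors left all 6 counts within 1.5 times; the last moves almost nothing, as the values were already scaled so. For SD70 the additive fit called 0 genes with limma without the trend, with no filter, with limma-voom and no filter, and without the trend and with no filter, and 2771 to 4119 in the other settings. For MI-503 it called 1 at a mean of at least 5 FPKM and 0 elsewhere. The correlation of SD70 and MI-503 folds was 0.71 at a mean of at least 5 FPKM and 0.72 in protein-coding genes. That of the SD70 pairs sharing no library was 0.51 and 0.81 with pseudocounts of 0.1 and 5, 0.53 with no filter, 0.87 at 5 FPKM, 0.89 in protein-coding genes and 0.85 with 20 reads, and that of the MI-503 pairs -0.22 in protein-coding genes. Interferon-stimulated genes turned from 0.15 to -0.02 for MI-503 at a mean of at least 5 FPKM, and immediate early genes from -0.28 to 0.01 with no filter. Of 204 list medians, 79 moved by more than their counting interval with the same FPKM total, 69 with the same read total, 22 and 84 with pseudocounts of 0.1 and 5, and 41 with no filter. At 5 FPKM there were fewer list medians, of which 44 moved, 1 reversed and 153 stayed the same. Of 123 named folds, 14, 18, 41 and 88 moved under the 2 totals and the 2 pseudocounts, and 0 changed sign. Leaving out a library leaves the additive fit no residual degree of freedom, so it has no such value. No paired analysis was possible because each group had 1 library. Depth limits low genes: at this depth a short gene at 1 FPKM rests on few reads, and counting noise alone gave 72.6 genes under 300 bases past 2-fold for MI-503, against 181 observed. The simulated number may be too small, since genes without reads in DMSO do not vary in it.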

Other observations

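The tests on granule genes and on targets of the aryl hydrocarbon receptor were chosen only after CYP1B1 and the granule list's values had been seen.

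Apart from the myeloid genes, SD70 left a mixed stress picture. BCL2A1, an anti-apoptotic gene driven by NF-kB, went from 0.243 to 6.65 FPKM in SD70 and stood at 1.29 in MI-503 and 4.69 in the combination. HMOX1 stood at 0.275, 4.19, 0.879 and 2.39 FPKM, whereas the chaperone genes HSPA5 (188, 54.4, 160 and 66.8) and HSP90AA1 (459, 143, 318 and 158) were lower in both SD70 libraries. ABCA1, the cholesterol exporter, was highest with MI-503 alone, at 2.02, 1.42, 6.46 and 1.17 FPKM.

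Granule genes may be an MI-503 response that SD70 leaves in place. A deviating DMSO library with no effect of MI-503 would not lift them in the combination against SD70, yet the list lay at percentile 99.98 there, with all 11 measured members higher in both pairs. Of the 34 lists with a median, this list and the mitosis list (lower) were the 2 that lay outside the range of 95% of random lists the same way in both MI-503 pairs, and 11 lay outside in opposite ways. Since 17 of the 34 lists lay outside that range in the combination against SD70, a chance difference between these 2 libraries stays open.

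CYP1B1, a target of the aryl hydrocarbon receptor, was at 19.8, 143, 36.0 and 102 FPKM, and a candidate explanation is that SD70 activates this receptor. Other targets were examined for it: AHRR stood at 22.1, 55.5, 27.3 and 47.6 FPKM (limma adjusted p = 0.0229) and TIPARP at 4.69, 8.54, 5.17 and 7.75 (adjusted p = 0.0318), while CYP1A1 had 2, 4, 0 and 5 reads and was too low to judge. The median log2 over the 3 genes was 0.74 in SD70 against DMSO and 0.5 in the combination against MI-503, at the bound of 0.5 set for this explanation. With 2 measured genes, the test stays weak.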
